A study of Mus musculus with 4 samples.

How the data were processed

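Gene expression was measured in 4 samples of round spermatids sorted from mouse testis (ICR background), 2 heterozygous for an altered Wfdc15a allele and 2 labelled as homozygous. Per the labels' protocols, the sorted cells were lysed, amplified with Smart-seq2 using 15 cycles of PCR, and tagmented with a Nextera XT kit, a protocol that keeps neither strand nor molecular identifiers. FastQC 0.11.8, Trim Galore 0.6.6, HISAT2 2.1.0 and the mm10 build are named in the submitters' processing notes. The counting tool, the annotation and any filter are not given in the sources used here. The gate of the sort is not described in them either.

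The authors deposited log2 RPM values, reads scaled to the total of each library, for 25965 genes with mm10 coordinates and no adjustment for gene length. Within each library the deposited values above the lowest step by whole reads, and the lowest value equals 0.9 of a read, so a gene with no read sits at a level that depends on the depth of its library. Taking the lowest value as 0.9 of a read, 99.7% to 100.0% of the other values per library came out whole within 0.01 of a read. The totals recovered this way were 5774112, 33853604, 21160061 and 11268909 reads for heterozygous controls 1 and 2 and knockouts 1 and 2, a 5.86-fold range. The listed genes held 95.2%, 97.0%, 96.5% and 95.1% of these reads, and 1 read was worth 0.173, 0.0295, 0.0473 and 0.0887 RPM. Counts of 2 were more frequent than counts of 1 in every library (1039 against 543 genes in heterozygous control 1), so both mates of a pair may have been counted. PCR reads without molecular identifiers are not independent molecules, and the floor of 3 reads covers counting error only. Of the listed symbols, 87.1% were found in GENCODE M21, and 99.6% of these overlapped its position.

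Groups and replicate numbers were taken from the sample titles. Genes at 1 RPM or more in at least 2 of the 4 libraries were tested (15888 genes). The groups were compared with limma 3.58.1 in R 4.3.3 on the log2 RPM values as deposited, with empirical Bayes moderation along a mean-variance trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A log2 difference of a gene with few reads depends on the value given to 0 reads, so folds are ratios of mean RPM, and a group with 0 reads in both libraries was set to 3 reads over both (0.0757 RPM for the heterozygous group). Of the tested genes, 17 had 0 reads in both heterozygous libraries and 0 had none in both libraries labelled knockout, and setting such genes to that bound left every list median as given.

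The text names Wfdc15a, then the genes with the largest differences among those passing, and, since fewer than 10 passed, the 10 per direction with the smallest p whose groups did not overlap, leaving out symbols made of Gm and a number or ending in Rik. From each list it names up to 4 members with the smallest p. The result of 1 such member is not reported here. The rule, the 29 lists, the comparisons and their tests and all alternatives except 3 were fixed before the data were examined, but the tests of explanations and of splits in the closing part and their further macrophage list were not. The 3 alternatives added later were a common lowest value, a crossed pairing of replicates and the lists without macrophage members.

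There were 29 lists holding 837 symbols, of which 788 matched the table as written, 33 by an older symbol at an overlapping position and 16 did not match. The 28 lists with at least 5 tested members were tested with limma's camera (preset correlation of 0.01 between genes), adjusted over the 28, and again with an estimated correlation and with fry. The list of mitochondrially encoded genes had 13 listed members with 0 reads in all libraries and was not tested. Genes of chromosomes X and Y, and genes within 1 Mb of Wfdc15a with Wfdc15a left out, were tested as groups in the same way.

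The code was tested on simulated data. In 5 simulated sets of 15888 genes with the depths of these libraries and negative binomial counts, 200 genes averaging 2 RPM or more were changed each time. The test recovered 41.2% of genes changed by 1 on the log2 scale, 85.2% of those changed by 2 and 99.2% of those changed by 3, with 22 false calls among 836. Folds added to the real libraries after removal of their group difference, in genes at a mean log2 RPM of 1 or more, were recovered in 0.4%, 51.6% and 78.4% of genes. Alternatives were 2 other scalings, log2(RPM + 1), no filter and a filter of 5 RPM, no variance trend, array weights, leaving out each library, a replicate block, voom on the recovered reads and other thresholds. Permutation tests on gene groups used 100000 resamples in SciPy 1.17.1 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.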

Results

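Round spermatids, the haploid male germ cells that follow meiosis and precede elongation, were sorted by flow cytometry from mouse testis of the outbred ICR background, and their messenger RNA was measured with the Smart-seq2 full-length protocol. The series compares cells of mice with 1 altered allele of Wfdc15a (genotype +/-, the controls, 2 libraries) with cells of mice labelled as lacking both intact alleles (genotype -/-, 2 libraries). Wfdc15a encodes a small protein with a WAP domain, a fold shared with several protease inhibitors. The design text also mentions wild-type controls, which were not analysed here. The deposited table listed 25965 genes in log2 RPM, reads scaled to the total of each library. Its steps gave library totals of 5774112 and 33853604 reads for heterozygous controls 1 and 2, and of 21160061 and 11268909 reads for knockouts 1 and 2. Nothing in the labels says whether the replicates came from separate animals, so p-values of single genes measure the spread between these samples, which may be technical. The camera p-values of gene groups set the genes of a group against all other tested genes, with a preset correlation between genes. They do not measure how far a group varies between samples. Group values below are mean ± SD of RPM over n = 2 libraries, and folds are ratios of those means.

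The targeted gene was examined first. Wfdc15a lies on chromosome 2 of the mm10 build from 164198863 to 164200130 on the minus strand, where GENCODE M21 annotates a protein-coding gene of 3 exons. Its transcript was present in all 4 libraries, at 121 and 85.2 RPM in the heterozygous libraries and at 82.6 and 59.5 RPM in the libraries labelled knockout. The difference was -0.53 on the log2 scale (SE 0.29, 95% confidence interval -1.17 to 0.10, limma adjusted p = 0.647) and did not pass, although both libraries labelled knockout lay below both heterozygous libraries. It was -0.28 without heterozygous control 1 (adjusted p = 0.809) and -0.30 without knockout 2 (adjusted p = 0.9996). An exact permutation test of 2 against 2 libraries gave p = 0.333 (two-sided), which is also the smallest p that this design allows. The labels do not say which part of the gene was altered, and a value summed over the gene cannot show the loss of part of it, so the genotype is given below as labelled.

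The main comparison asked which transcripts differ between spermatids labelled knockout and heterozygous spermatids. Immediate early transcription factors and genes of macrophages were among the genes with the smallest p on the higher side, and genes of proteins that replace histones in late spermatids on the lower side, but no single gene passed the test. Fos, an immediate early gene, had 0 reads in both heterozygous libraries and 26.3 and 14.6 RPM in the libraries labelled knockout. Their mean was 270.0-fold the 0.0757 RPM that 3 reads over both heterozygous libraries would give. If both mates of a pair were counted, 3 reads are not a bound for a count of 0, and the fold may be lower. Atf3, another stress-induced transcription factor gene, was at 0.148 ± 0.209 RPM in heterozygous and 12.6 ± 4.48 RPM in knockout-labelled libraries (log2 difference 5.83, SE 0.83, adjusted p = 0.202). Tnp2, which encodes transition protein 2, was at 488 ± 134 RPM against 150.2 ± 32.9 RPM (log2 difference -1.69, SE 0.26, adjusted p = 0.222). Of 15888 genes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.202. At an unadjusted p under 0.05 there were 1283 genes, 986 higher and 297 lower, where 794 would be expected by chance, and voom weights on the recovered reads gave 0 passing genes and 1961 at an unadjusted p under 0.05. The share of higher genes among the 1283 was 76.9%, and it was 64.0% after median-ratio scaling and 55.9% after quantile normalization. Leaving out 1 library could change the number of passing genes, but such a fit takes its spread from the other group alone. A deviation of the lone library then counts as a group difference. These numbers are given below with the dependence on processing.

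Both libraries labelled knockout lay above both heterozygous libraries for 23.5% of tested genes and below both for 15.0%, where chance gives 16.7% each. Values on the log2 scale correlated across genes at r = 0.921 between the heterozygous libraries, at r = 0.952 between the libraries labelled knockout, and at 0.917 to 0.929 across the groups.

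The 10 named genes per direction are those with the smallest p whose groups did not overlap, and none of them passed with the 1 RPM filter. A fit without a filter takes part of its variance estimate from genes with 0 reads (4648 to 7647 per library), whose level is set by depth. In that fit all 20 passed, among 180 genes. On the higher side, besides Fos and Atf3, they included H2-Aa, a class II antigen presentation gene (0.520 and 0.177 against 35.3 and 6.66 RPM), Lyz2, the lysozyme gene of macrophages (0.741 ± 0.421 against 22.8 ± 20.9 RPM), Mrc1, the macrophage mannose receptor (1.06 ± 0.761 against 12.8 ± 5.23 RPM), and Cybb, a subunit of the phagocyte oxidase (0.0591 ± 0.0836 against 8.22 ± 4.22 RPM). Insl3, a hormone gene of Leydig cells (0.671 ± 0.0303 against 13.8 ± 8.80 RPM), and Trf, the transferrin gene (0.644 ± 0.176 against 8.43 ± 1.25 RPM), mark other somatic cells of the testis. Dock4, a guanine nucleotide exchange factor gene, was 6.68-fold higher and Txnip, the thioredoxin-interacting protein gene, 5.88-fold higher. Insl3, Trf and Txnip overlap other listed genes (Jak3, Gm20425 and Gm15441), and their reads may be shared, since the counting rule is not given in the sources used here.

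On the lower side, Prm1, a protamine gene, was at 730 ± 284 RPM in heterozygous and 266 ± 60.7 RPM in knockout-labelled libraries (log2 difference -1.42, SE 0.28, adjusted p = 0.295). Odf3b was 5.04-fold lower, Tmsb10, a thymosin that binds actin monomers, 2.59-fold lower, and Pfn2, a profilin gene, 2.52-fold lower. Ssxb3 was at 26.0 and 11.9 RPM in heterozygous and 2.50 and 3.99 RPM in knockout-labelled libraries, and it belongs to an X-linked family of similar copies among which reads can be misassigned. Plcl1, Ckap4 and Nudt4 were lower by 2.50-fold, 2.45-fold and 2.13-fold, and Btbd1 was at 532 and 564 RPM against 148 and 311 RPM.

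**Figure D1:**
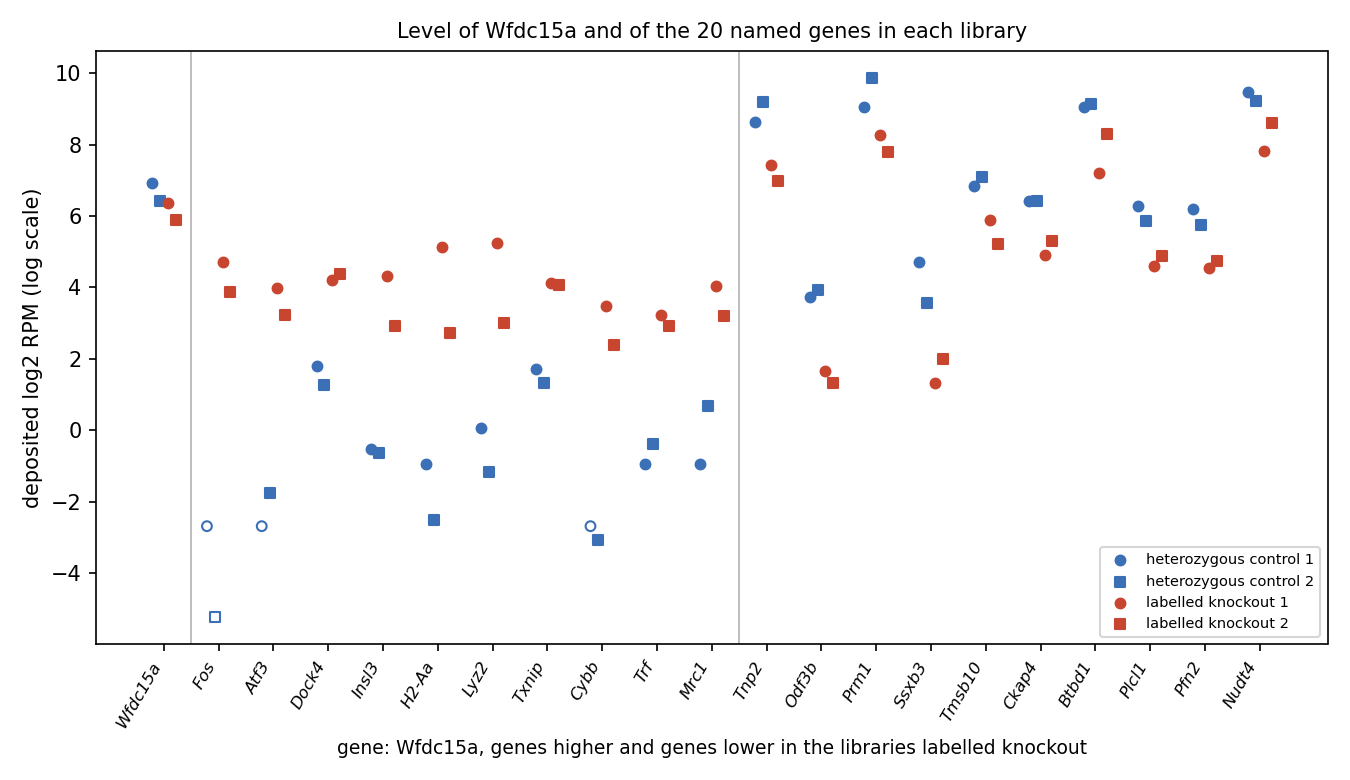
Deposited log2 RPM (vertical axis, a log scale) of Wfdc15a and the 20 named genes in each of the 4 libraries. Blue points are the heterozygous libraries, red points the libraries labelled knockout, circles replicate 1, squares replicate 2, and open symbols genes with 0 reads, drawn at the lowest value of that library. Wfdc15a was at 82.6 and 59.5 RPM in the libraries labelled knockout, while Fos had 0 reads in both heterozygous libraries.

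Lists of genes fixed before the data were examined were compared as groups, since the series' title names protease and immune homeostasis. Macrophage markers were the group furthest apart. Their median log2 difference was 3.78 over 20 tested genes, 15 lay above both heterozygous libraries and 0 below, and the list rose as a whole (camera adjusted p = 3.86e-17, or adjusted p = 0.656 with an estimated correlation). With log2(RPM + 1), which depends less on the value given to 0 reads, the median was 2.03. No member passed over all genes tested, and 15 passed when adjusted over the list alone. Besides H2-Aa, Lyz2 and Mrc1, these included Ctss, the gene of the antigen-processing protease cathepsin S, which had 0 reads and 1 read in the heterozygous libraries and 16.4 and 4.79 RPM in those labelled knockout. Cd74, the invariant chain gene, which was chosen after its values were seen, was at 4.50 and 0 RPM against 133 and 31.1 RPM. Cx3cr1 and Aif1, also chosen after their values were seen, were abundant in every library, at 987 to 1116 RPM and 316 to 558 RPM, and 5 of the 20 markers were at 10 RPM or more in the heterozygous mean.

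Cathepsins and lysosomal proteases rose as a list, with a median of 1.73 over 15 genes (adjusted p = 7.75e-09, or adjusted p = 0.656 with an estimated correlation). The median was 1.07 without heterozygous control 2, 1.0005 without knockout 1 and 0.89 with the 5 RPM filter, and the list passed in each case. Of its genes, 12 lay above both heterozygous libraries and 0 below, and 8 passed when adjusted over the list alone. Ctsc was at 0.346 and 0.561 RPM against 10.3 and 4.79 RPM, Ctsb at 1.73 and 1.95 RPM against 24.1 and 7.45 RPM, and Ctsa at 1.73 and 1.12 RPM against 17.5 and 3.73 RPM, highest each time in knockout 1, and 1 member, Ctss, is also a macrophage marker. Complement and defensin genes rose with a median of 0.72 over 22 genes (adjusted p = 6.19e-06, or adjusted p = 0.656 with an estimated correlation). Of these, 8 passed when adjusted over the list alone. They included Lyz2 and the complement genes C1qa and C1qb, which with C1qc are the 4 members shared with the macrophage list. Cytokines and inflammatory signalling genes rose with a median of 1.08 over 25 genes (adjusted p = 2.84e-04, or adjusted p = 0.656 with an estimated correlation), although 0 members passed when adjusted over the list alone. That median was 0.58 without heterozygous control 2, 0.38 with quantile normalization and 0.51 with log2(RPM + 1), each passing. Il1b, the interleukin-1 beta gene, was at 0.173 and 1.30 RPM against 10.02 and 3.46 RPM, and Relb, a subunit of NF-kappaB, was 3.34-fold higher. Cxcl2 had 0 reads in both heterozygous libraries, and its mean in those labelled knockout was 36.7-fold the level that 3 reads over both would give. With 5 RPM as the minimum, fewer than 5 cytokine genes were left and that list had no value.

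Interferon response genes, class I antigen presentation genes and the lymphocyte and neutrophil markers did not pass. Their medians were 0.08 over 11 genes (adjusted p = 0.722), 0.21 over 14 genes (adjusted p = 0.539) and 1.17 over 6 genes (adjusted p = 0.0953). Of the last list, Coro1a, a coronin gene of blood cells, had 0 reads in both heterozygous libraries and 4.58 and 6.74 RPM in those labelled knockout, and 1 member passed when adjusted over the list alone. The interferon and class I medians were 0.50 and 0.041 without heterozygous control 1, -0.32 and 0.40 without heterozygous control 2, and -0.24 and -0.022 with quantile normalization, so neither had a stable direction. The lymphocyte and neutrophil list passed without heterozygous control 2 (median 2.26, adjusted p = 0.0189) and without a variance trend (adjusted p = 0.0359). H2-D1, a class I gene, was 2.74-fold higher and B2m, which encodes its light chain, was at 7.45 and 3.16 RPM against 11.6 and 16.1 RPM.

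Among markers of the other testis cells, Leydig and spermatogonial genes rose as lists. Leydig markers had a median of 1.88 over 9 genes (adjusted p = 0.0233, or adjusted p = 0.656 with an estimated correlation), with 2 members, Insl3 and the steroid enzyme gene Cyp17a1, passing when adjusted over the list alone. Spermatogonial markers had a median of 1.03 over 18 genes (adjusted p = 0.0165, or adjusted p = 0.656 with an estimated correlation) with 0 members passing when adjusted over the list alone. Kit, a receptor of differentiating spermatogonia, was at 7.96 ± 3.69 against 15.5 ± 2.57 RPM, and Dmrtb1 was lower, at 239 ± 4.89 against 169 ± 17.8 RPM. Both calls ended without heterozygous control 2 (medians 0.68 and 0.64, adjusted p = 0.0706 and 0.114) or without knockout 1 (adjusted p = 0.183 and 0.140), and with quantile normalization (medians 1.17 and 0.60, adjusted p = 0.0506 and 0.0521). With log2(RPM + 1) the medians were 1.01 and 0.60, both passing. The Leydig call also ended without a variance trend (adjusted p = 0.116), and the spermatogonial call with the 5 RPM filter (median 0.45, adjusted p = 0.189). Sertoli markers (median 0.77 over 17 genes, adjusted p = 0.195), peritubular and stromal markers (median 1.12 over 12 genes, adjusted p = 0.0753) and blood and endothelial markers (median -0.28 over 9 genes, adjusted p = 0.722) did not pass. The peritubular and stromal list passed without heterozygous control 1 (median 1.99, adjusted p = 1.01e-06), without knockout 1 (median 1.02, adjusted p = 0.0395) and without a filter (adjusted p = 2.81e-04), while its median was -0.11 without heterozygous control 2. The Sertoli list passed without heterozygous control 2 (median 0.44, adjusted p = 0.0189) and had a median of -0.065 without heterozygous control 1 (adjusted p = 0.792). The blood and endothelial median was 0.11 without heterozygous control 2. Trf was the 1 Sertoli gene that passed when adjusted over the list alone.

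**Figure D2:**
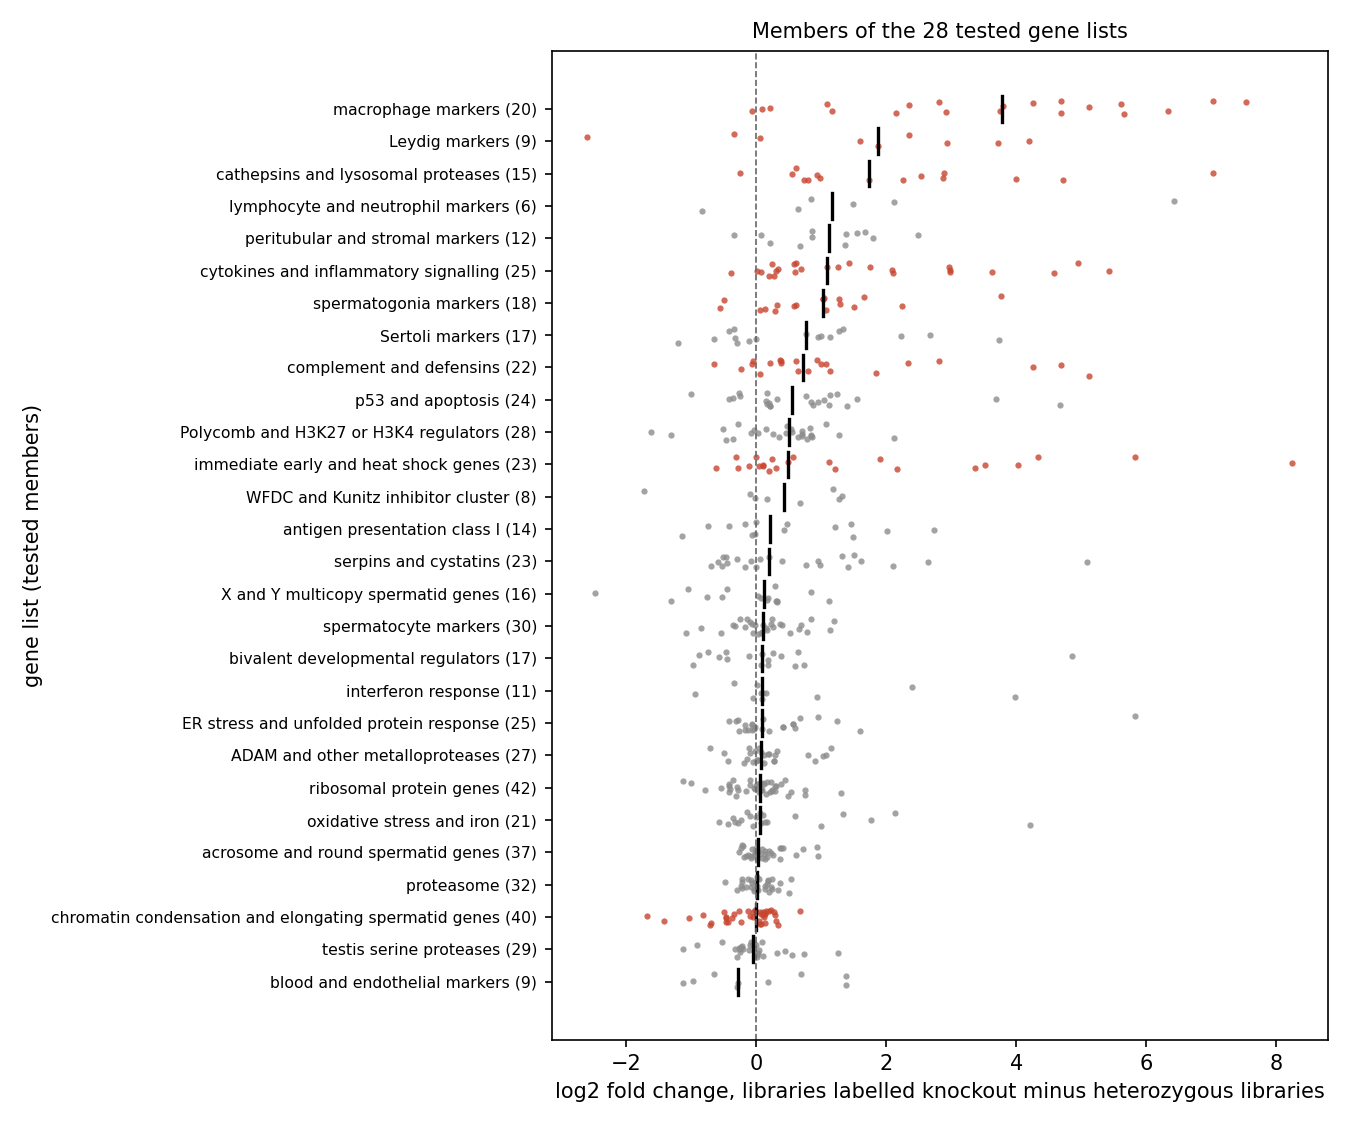
Log2 fold change of every tested member (points) of the 28 lists, libraries labelled knockout minus heterozygous libraries, with the list median as a black bar and the number of tested members in parentheses. Red lists passed camera with the preset correlation and gray lists did not. Macrophage markers had the highest median, 3.78, and acrosome genes stayed close to 0, at 0.02.

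Among genes of the spermatids themselves, only the list of chromatin condensation genes passed, and in the lower direction. Acrosome and round spermatid genes had a median of 0.02 over 37 genes (adjusted p = 0.539), of which 3 were higher at an unadjusted p under 0.05, among them Hyal5, a sperm hyaluronidase gene (137 ± 26.6 against 224 ± 32.5 RPM), and the list passed without heterozygous control 2 (median 0.22, adjusted p = 0.0189). Chromatin condensation and elongating spermatid genes fell by the list test (adjusted p = 0.01, or adjusted p = 0.926 with an estimated correlation), although their median was -0.01 over 40 genes and their mean -0.17. The members that were lower at an unadjusted p under 0.05 were the 5 genes of transition proteins and protamines, Tnp2, Prm1, Tnp1 (609 ± 270.1 against 289 ± 82.4 RPM), Prm2 (1005 ± 540 against 571 ± 65.8 RPM) and Prm3, of which Tnp2 and Prm1 passed when adjusted over the list alone. The fall of these 5 genes leaned on heterozygous control 2: their median was -1.03, but -0.56 without it, and Prm2 was at 624 RPM in heterozygous control 1 beside 618 and 525 RPM in the libraries labelled knockout. Without heterozygous control 1 the list median was -0.32 (adjusted p = 4.19e-17), without heterozygous control 2 it was 0.20 (adjusted p = 0.114), without knockout 2 it was 0.00 (adjusted p = 0.0651), and after quantile normalization it was 0.01 (adjusted p = 0.249). Spermatocyte markers (median 0.10 over 30 genes, adjusted p = 0.810) and the X and Y multicopy spermatid genes (median 0.12 over 16 genes, mean -0.18, adjusted p = 0.194) did not pass, though 3 of the latter, the related copies Ssxb3, Ssxb1 and Ssxb2, were lower at an unadjusted p under 0.05. Both of these lists passed without heterozygous control 1 (medians 0.27 and -0.10, adjusted p = 0.0489 each), and the spermatocyte median was -0.16 without heterozygous control 2.

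Immediate early and heat shock genes rose as a list, with a median of 0.49 over 23 genes (adjusted p = 1.86e-05, or adjusted p = 0.656 with an estimated correlation). The median was 0.78 without heterozygous control 2. Of these genes, 7 passed when adjusted over the list alone, including Fos, Atf3, Klf6 (0.350 ± 0.00572 against 7.54 ± 3.77 RPM) and Egr1 (0.741 ± 0.421 against 7.83 ± 0.978 RPM), transcription factor genes that respond within minutes to growth factors or stress. The macrophage markers were higher in the same libraries, with the median of 3.78 given above. Genes of the unfolded protein response (median 0.08 over 25 genes, adjusted p = 0.282) and of p53 and apoptosis (median 0.55 over 24 genes, adjusted p = 0.104) did not pass, though the latter passed without heterozygous control 1 (median 0.79, adjusted p = 0.00259) and without a filter (adjusted p = 0.0165), and its median was -0.10 without heterozygous control 2. Atf4, a transcription factor gene of the unfolded protein response, was 3.07-fold higher.

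Apart from the cathepsin and lysosomal protease list given above, the protease and inhibitor lists did not pass with all 4 libraries. The WFDC and Kunitz inhibitor cluster had a median of 0.42 over 8 genes (adjusted p = 0.810), with Wfdc6a at 2.43 ± 0.246 against 0.730 ± 0.0969 RPM and Wfdc9 at 1.54 ± 0.459 against 3.64 ± 0.129 RPM. Serpins and cystatins had a median of 0.20 over 23 genes (adjusted p = 0.996), testis serine proteases a median of -0.06 over 29 genes (adjusted p = 0.195), and ADAM and other metalloproteases a median of 0.07 over 27 genes (adjusted p = 0.539). The serpin and cystatin median turned to -0.069 without heterozygous control 1 and to -0.13 with the 5 RPM filter, and the median of the inhibitor cluster to -0.15 without knockout 1. The testis serine protease list passed downward without heterozygous control 1 (median -0.09, adjusted p = 0.0330) and without knockout 1 (median -0.18, adjusted p = 0.0256). Cst3, the cystatin C gene, was at 18.2 and 9.95 RPM against 50.1 and 22.5 RPM, Prss58 was 1.89-fold lower, and Adam6a was 1.99-fold higher. Bivalent developmental regulators, named because the title calls Wfdc15a a bivalent gene, had a median of 0.09 over 17 genes (adjusted p = 0.539). At an unadjusted p under 0.05, 1 member was higher and 2 were lower. Wnt3 and Gata2 were 1.87-fold and 1.68-fold lower. Folds were also added to single genes at a mean log2 RPM of 1 or more, with the spread of the real libraries. Of genes changed by 1 on the log2 scale 0.4% were recovered, of those changed by 2 51.6% and of those changed by 3 78.4%. Many single-gene differences of these sizes would thus be missed. In this test the other genes kept no group difference, and many genes were changed at once, which eases the adjusted threshold. The rates may therefore be too high for the real comparison, where no gene passed. They also do not cover genes at lower levels or the tests of lists.

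Round spermatids carry either an X or a Y chromosome, so both were compared with the autosomes. X-linked genes rose as a group, with a median of 0.30 over 599 genes against 0.06 over 15237 autosomal genes (camera adjusted p = 0.00996, or adjusted p = 0.153 with an estimated correlation). The median was 0.14 with quantile normalization and 0.18 with the 5 RPM filter, both passing. Cybb, the X-linked gene with the highest difference (5.82), is a gene of macrophages, whose markers rose in the same libraries. Y-linked genes fell, with a median of -0.14 over 52 genes (camera adjusted p = 0.0291, or adjusted p = 0.169 with an estimated correlation). Of these, 13 lay below both heterozygous libraries and 5 above. The summed RPM of Y-linked genes overlapped between the groups, at 528 and 439 in heterozygous and 415 and 514 in knockout-labelled libraries. The call for Y ended without heterozygous control 1 (median -0.042, adjusted p = 0.0954), heterozygous control 2 (median -0.24, adjusted p = 0.0590) or knockout 1 (median -0.071, adjusted p = 0.213). It also ended with median-ratio scaling (adjusted p = 0.0570) and with the 5 RPM filter (adjusted p = 0.275).

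Genes within 1 Mb of Wfdc15a were compared because an altered allele can travel with a linked stretch of chromosome in an outbred background. The median log2 difference of 46 tested neighbours was 0.14, and the group did not pass camera. Of these, 17 lay above both heterozygous libraries and 5 below, against 23.5% above and 15.0% below over all tested genes. The group passed fry's mixed test, which takes no direction, but not its directional test. That 0 of its genes passed is not informative, since no gene passed in the whole comparison. Ctsa, also a member of the cathepsin list, was the neighbour with the smallest p, at 1.43 ± 0.431 against 10.6 ± 9.76 RPM.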

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

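The crossed pairing, the common lowest value and the lists without macrophage members were chosen after the data were seen. The 0 passing genes stayed 0 under both scalings, the 5 RPM filter, no variance trend, array weights, a common lowest value, voom and an adjusted p of 0.1, but became 1 with log2(RPM + 1) and 180 without a filter, the 20 named genes included. The fit without a filter takes part of its variance estimate from genes with 0 reads, whose level is set by depth. How far this raised the 180 was not tested. Leaving out a library gave 0 to 558 (442 without heterozygous control 1, 558 without heterozygous control 2, 0 without knockout 1, 5 without knockout 2), where the lone library of a group is assumed to vary like the other group. Without a heterozygous library the spread rests on the pair labelled knockout, whose SD was 0.56 against 0.79 for the heterozygous pair. With the replicate block there were 66 genes. Same-numbered libraries did not deviate together (r = -0.08 across tested genes, r = -0.30 over the 9220 at a mean log2 RPM of 3 or more). Depth ran in opposite order in the heterozygous pair and the pair labelled knockout, which could itself lower r. Whether the numbers pair the samples is therefore not known. The crossed pairing gave 404.

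The 8 lists that passed became 5 with quantile normalization, 5 with the 5 RPM filter (22 lists had a value), 0 with an estimated correlation and 0 with fry's directional test, and leaving out a library gave 8 to 14, for causes not tested. Of the 8, the calls kept were 8 without heterozygous control 1, 5 without heterozygous control 2, 6 without knockout 1 and 7 without knockout 2, and 7 without a variance trend. Fry's mixed test, which takes no direction, called 8, of which the cytokine, complement, spermatogonial and immediate early lists were among the 8 of camera. The macrophage list aside, leaving out its members took 1 gene from the cathepsin list and 4 from the complement list. It took none from the other called lists. The cathepsin and complement calls remained, with medians of 1.36 (adjusted p = 1.98e-07) and 0.49 (adjusted p = 0.00714). This does not show that their rise was separate from that of the macrophage markers. The block ended no call of a list. Macrophage markers, cathepsins, complement and immediate early genes passed in every refit with the preset correlation. The Y median was -0.22 with median-ratio scaling, -0.17 with the 5 RPM filter and -0.14 with the crossed pairing, none passing, and -0.24 to -0.042 when a library was left out, and the cause was not tested. The condensation list turned upward without heterozygous control 2 (median 0.20, range -0.32 to 0.20 over the libraries left out), and the ribosomal list passed upward without knockout 2 (median 0.35) but downward without knockout 1 (median -0.26), with the cause not tested. Wfdc15a (-0.79 to -0.28 when a library was left out), X and the neighbourhood kept direction and side of the threshold in every refit with the preset correlation (X had an adjusted p of 0.153 with an estimated correlation), as did the direction of all named genes (280 values, 97 past the threshold). Low levels limit precision: the median absolute log2 difference was 1.55 for genes averaging under 1 RPM and 0.22 for those at 10 RPM or more.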

Other observations

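The tests of explanations and of splits in this part were chosen after the results were seen, and the list tests in this paragraph were not. The oxidative stress and iron list did not pass (median 0.06 over 21 genes, adjusted p = 0.539), except without knockout 2 (median 0.16, adjusted p = 0.0400). Of its members, Ftl1, the ferritin light chain gene, was at 8.55 ± 4.07 RPM in heterozygous and 38.4 ± 20.7 RPM in knockout-labelled libraries and passed when adjusted over the list alone, and Fth1, the heavy chain gene, was at 29.1 ± 2.17 against 58.0 ± 6.02 RPM. Hmox1, which encodes the haem-degrading enzyme, was at 0 and 0.118 RPM against 5.95 and 1.06 RPM. Ribosomal protein genes went both ways (median 0.06 over 42 genes, adjusted p = 0.539), with Rps29 and Rps27 1.97-fold and 1.72-fold lower, Rpl38 at 63.9 and 50.5 RPM against 38.2 and 17.7 RPM, and Rpl7 1.45-fold higher, and the list passed downward without knockout 1 (median -0.26) and upward without knockout 2 (median 0.35). Proteasome genes (median 0.01 over 32 genes, adjusted p = 0.722) and Polycomb and histone methylation regulators (median 0.50 over 28 genes, adjusted p = 0.282) did not pass, though the regulators passed without heterozygous control 1 (median 0.72, adjusted p = 0.0120) and had a median of -0.021 without heterozygous control 2. Dnmt3l, a cofactor of DNA methylation, was 2.42-fold lower and Dnmt1, the maintenance methyltransferase gene, was at 6.58 and 3.81 RPM against 18.6 and 7.81 RPM.

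The 4 libraries can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The real split called 8 lists, and the highest of the others called 9, so that 2 of the 3 splits, the real one included, gave as many. The macrophage median was 3.78 in the real split and 1.32 and -0.27 in the others, and there were 1283 genes at an unadjusted p under 0.05 in the real split against 180 and 1000.

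Macrophage genes were higher in both libraries labelled knockout. Depth and the value given to 0 reads do not account for this, since with 1 lowest value for all libraries the median stayed at 3.62 (quartiles 1.53 and 4.48), and the deepest and the shallowest library were both heterozygous. A lower share of spermatids that raised every other cell type alike cannot be excluded. Macrophage markers under 10 RPM (10 genes, mean over all libraries) had a median log2 difference of 4.48. Such markers of Sertoli, Leydig, peritubular and endothelial cells (35 genes) had a median of 0.95. The medians differed by 3.52 (two-sided permutation p = 2e-05, the smallest that the resamples can give, across genes that are not independent). However, a fold depends on the heterozygous level, for which the groups were not matched. The Leydig gene Insl3 and the Sertoli gene Trf, which overlap other listed genes, rose by 4.19 and 3.73, the highest values of their lists. Those lists reached down to -2.61 and -1.21. Of 9 Leydig markers 5 lay above both heterozygous libraries and 2 below, and of 17 Sertoli markers 6 above and 2 below. Macrophage RNA carried into the sort is a candidate explanation. Of 43 macrophage genes from a further list, taken without a filter, 28 lay above both heterozygous libraries and 1 below, against 19.2% above over all listed genes. Of the 43, 3 were at 10 RPM or more in the heterozygous mean. The list was written after the results were seen and holds Cybb, a gene already named as higher. Its count repeats the pattern and does not tell carried-over RNA from the other explanations. The most abundant marker that differed, Cd74, reached 133 RPM. A spermatid gate should remove macrophages, and more macrophages in the testes labelled knockout, a different gate between samples, or expression in the spermatids themselves stay open and untested.

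The 5 transition protein and protamine genes were lower, by a median of -1.03 (range -1.69 to -0.71), or of -0.56 (range -1.41 to -0.13) without heterozygous control 2. Dilution of spermatid RNA by other RNA would lower acrosome genes as much, and their median was 0.0231 (quartiles -0.07 and 0.23), or 0.22 without heterozygous control 2. Without heterozygous control 1 the acrosome median was -0.05 (lower quartile -0.26), where that of the 5 genes was -1.50. Loss of short transcripts as the whole cause is argued against, as the 91 other genes averaging 50 RPM or more with transcripts of up to 674 nt had a median of -0.15 (quartiles -0.35 and 0.01), but without heterozygous control 2 their lower quartile, -0.43, overlapped the 5 genes. Fewer late round spermatids in the sort may be the source and cannot be told apart from an effect of the genotype, because the other 35 genes of the condensation list went both ways (median 0.0516, quartiles -0.25 and 0.14). The genotype stays untested among the open explanations.

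Immediate early genes were higher, with 9 of 15 above both heterozygous libraries. RNA brought by macrophages in a fixed ratio cannot be told apart from other causes. The log2 ratio of knockout 1 to knockout 2 had a median of 1.27 (range 0.37 to 2.41) over 16 macrophage markers and of 0.61 (range -0.26 to 1.06) over 8 immediate early genes that were higher at an unadjusted p under 0.05, but this difference of 0.66 rests on 1 library against 1 and the ranges overlap. Longer handling of the samples labelled knockout cannot be told apart from the genotype, since handling is not recorded apart from the groups, and 2 of 8 heat shock genes lay above both heterozygous libraries and 1 below. An effect of the genotype stays among the open explanations, untested.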
